A study of Mus musculus with 58 samples.

How the data were processed

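RNA was sequenced from frozen mature mouse sperm in 58 libraries, 1 per sample. The labels give each sample a surgery group (surgery, or control, called no surgery here), a treatment (defeat or none), an si group (susceptible or resilient, for defeated mice) and a time point before or after defeat (pre or post). The kind of surgery is not given in the sources used here. In the cohort with surgery, 20 mice gave both a pre and a post sample, which makes 40 libraries in 6 groups. In the cohort without surgery, 18 other mice gave a post sample only, in 3 groups. Per the labels, RNA was extracted with TRIzol and an RNeasy kit, treated with DNase, made into ribosomal-RNA-depleted stranded total RNA libraries and sequenced on a HiSeq 2500. The labels give 2 read configurations, paired 150 bp reads and single 50 bp reads, which contradict each other.

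The deposited files hold raw counts, made by the authors with featureCounts 1.6.2 per the file headers. Fragments were counted over the whole span of each gene, introns included, without regard to strand, in the Ensembl release 90 annotation of GRCm38. The alignments counted had names saying that duplicates were removed, and the aligner is not given in the sources used here. The processing notes name DESeq2 without a version. The analysis started from the raw counts. Because strand was not used, a gene that overlaps another gene carries an uncertain share of its neighbour's reads, and 23724 of the 52636 counted genes overlap another. Gene names, biotypes and coordinates came from the GENCODE M21 annotation of GRCm38, which matched 52489 genes (99.7%) and left 147 unmatched.

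Libraries held 5414323 to 23890305 counted fragments with a median of 13618700, and 17934 to 28561 genes with at least 1 count. All 159 pairs of libraries within groups were compared for shared origin, and the chi-square per degree of freedom was 17.7 to 907, far above the value of 1 that repeated sequencing of the same library would give. Replicates are therefore separate libraries, and in the surgery cohort pre and post samples with the same mouse number were paired. Across genes, the deviations of a mouse's pre and post library from their group means correlated at r of −0.73 to 0.91 with a median of −0.02, above 0.1 for 9 of 20 mice. A pre library correlated best with its own mouse's post library for 3 of 20. For mouse 61, an undefeated mouse, the sample titles and the deposited file names give opposite time points. The titles were followed. Gene calls, profile shifts, correlations of changes, differences between cohorts and the fat cell and macrophage lists were also computed without this mouse, but the other list tests of each comparison and the splits were in part computed only with it.

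Counts were analysed with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood F test, TMM scaling, the filterByExpr filter, two-sided) with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. All 40 surgery libraries were fitted together as 6 group means with 21106 genes. The 18 libraries without surgery were fitted as 3 group means with 17046 genes, and the 12 post libraries of undefeated mice as 2 group means with 16572 genes. The fits gave 14 comparisons, and mice were not used as a block except in an alternative. Fold changes are log2 values with their standard error, and group levels are counts scaled to library size (CPM) as mean ± SD. Counts were simulated with 200 changed genes, each gene drawn independently at the same group sizes and with its own spread. For susceptible mice post against pre the test recovered 41.8% of 4-fold changes and 75.8% of 8-fold changes, with 2 false calls among 20906 unchanged genes. It recovered 59.7% and 87.9% for susceptible against undefeated mice without surgery, with 7 false calls. For surgery against no surgery it recovered 62.7% and 84.8%, with 4 false calls. Genes that move together between libraries were not simulated, so false calls can be more frequent in the real data. Other splits of the real samples called up to 8133 genes for susceptible mice post against pre.

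Whether the whole profile moved within mice was tested with an exact two-sided sign-flip permutation test over mice of the squared mean change in log2(CPM + 1). Agreement of changes between groups was measured across genes with Pearson's r and Spearman's rho, and because genes are not independent replicates the null came from flips of mice or, between cohorts, from 100 permuted groupings. The 5 correlations were adjusted together. A planned overlap of called genes between cohorts by Fisher's exact test could not be run, because the surgery cohort had no called gene in the comparisons concerned.

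Gene lists fixed before the data were examined covered late spermatid and sperm transcripts, acrosome and round spermatid transcripts, meiotic germ cell transcripts, epididymal epithelium, seminal vesicle and prostate, leukocytes, red blood cells, smooth muscle and connective tissue, fat cells and endothelium. They also covered glucocorticoid responsive genes, immediate early and heat shock genes, interferon response, DNA and RNA methylation enzymes, mitochondrially encoded transcripts, cytosolic ribosomal proteins and nuclear encoded respiratory chain subunits. These 17 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. This was done in 10 comparisons planned before and 4 added after the data were seen. The calls of list members were counted over all genes tested and again adjusted over the list alone. The level of a list in a library is the mean log2(CPM + 1) of its genes. Levels were compared between groups with exact permutation tests, by sign flips within mice for post against pre, adjusted over the lists of the same kind. Enrichment of long noncoding RNAs among called genes against protein-coding genes used Fisher's exact test. That test counts genes as independent, which they are not, so its p-values do not measure evidence over mice.

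The genes named were chosen by a rule fixed before the data were examined. In the post against pre comparisons and the post comparisons with undefeated mice, it took in each direction the 10 called genes with the largest fold change. These had an average log2 CPM of at least 1 and, for post against pre, the same direction in at least 5 mice. In the other comparisons it took 3 per direction. Where fewer than 5 genes were called it took the 3 smallest p per direction, and it added up to 4 members of each list with the smallest p. Figures and text show part of these. Some genes that this rule took are not reported here. The genes of the macrophage list in the closing section were chosen after the main results were seen.

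Alternatives fixed before the data were examined were DESeq2 1.42.0, size factors of the DESeq2 type (RLE) in edgeR, no filter on low counts, and only the groups compared in the fit. Further such alternatives were a score of the other cell types as a covariate, the mouse as a replicate block, mouse 61 left out, the 4 mice titled ER or D left out, and for the profile tests a pseudocount of 0.25 or a mean CPM of at least 10. Alternatives added after the data were seen were the scores of 4 cell lists as covariates, libraries with over 50% of counts in 10 genes left out, and each mouse left out in turn. The fat cell list was also tested without mouse 61, 69 or both, and the macrophage list without mouse 61 and without 2 members seen before it was written. The differences and correlations between cohorts were also computed without mouse 61 (the correlations without a permutation test). Further additions were named genes without mouse 61, all lists without mouse 11, the macrophage list without members near the floor, and each susceptible mouse alone against undefeated mice without surgery. The median log2 change of all genes differed by over 0.1 between TMM and RLE in 5 comparisons, and by less in the other 9. The TMM and RLE values were −0.13 and −0.28 for susceptible mice post against pre, −0.03 and −0.18 for the susceptible minus undefeated change. They were −0.04 and −0.26 for the susceptible minus resilient change, 0.06 and −0.16 for susceptible against undefeated mice post surgery, and 0.10 and −0.11 for susceptible against resilient mice post surgery. Changes are given on the TMM scale and are to be read against these medians. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.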

Results

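Total RNA of mature mouse sperm was sequenced in 58 libraries from mice classed as susceptible or resilient to defeat, a stress exposure, or left undefeated. In the cohort with surgery, sperm from the same mice was collected before and after (7 susceptible, 7 resilient and 6 undefeated mice). In the cohort without surgery, sperm was collected after only, from 6 mice of each class. The median depth of a group ran from 10494900 counted fragments (undefeated without surgery, 5414323 to 13705902) to 18043300 (resilient post surgery, 10573817 to 22170324). It was 13478900 and 15757800 in susceptible mice pre and post, 14105300 in resilient mice pre, and 17011200 and 13018300 in undefeated mice pre and post. It was 14384000 and 11671800 in susceptible and resilient mice without surgery. Mitochondrial 16S ribosomal RNA (mt-Rnr2) took 0.630% to 41.4% of a library. Within the span of Lars2, a leucyl-tRNA synthetase gene, counts reached 21.8% of a library, so that libraries differed in how much of their depth was left for other genes. The standard errors given below come from the spread between libraries within all groups of a fit. In that fit the pre and post libraries of a mouse counted as independent. They are therefore not the spread of changes within mice, nor that of the compared groups alone. The counts are fragments rather than independent molecules.

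**Figure D1:**
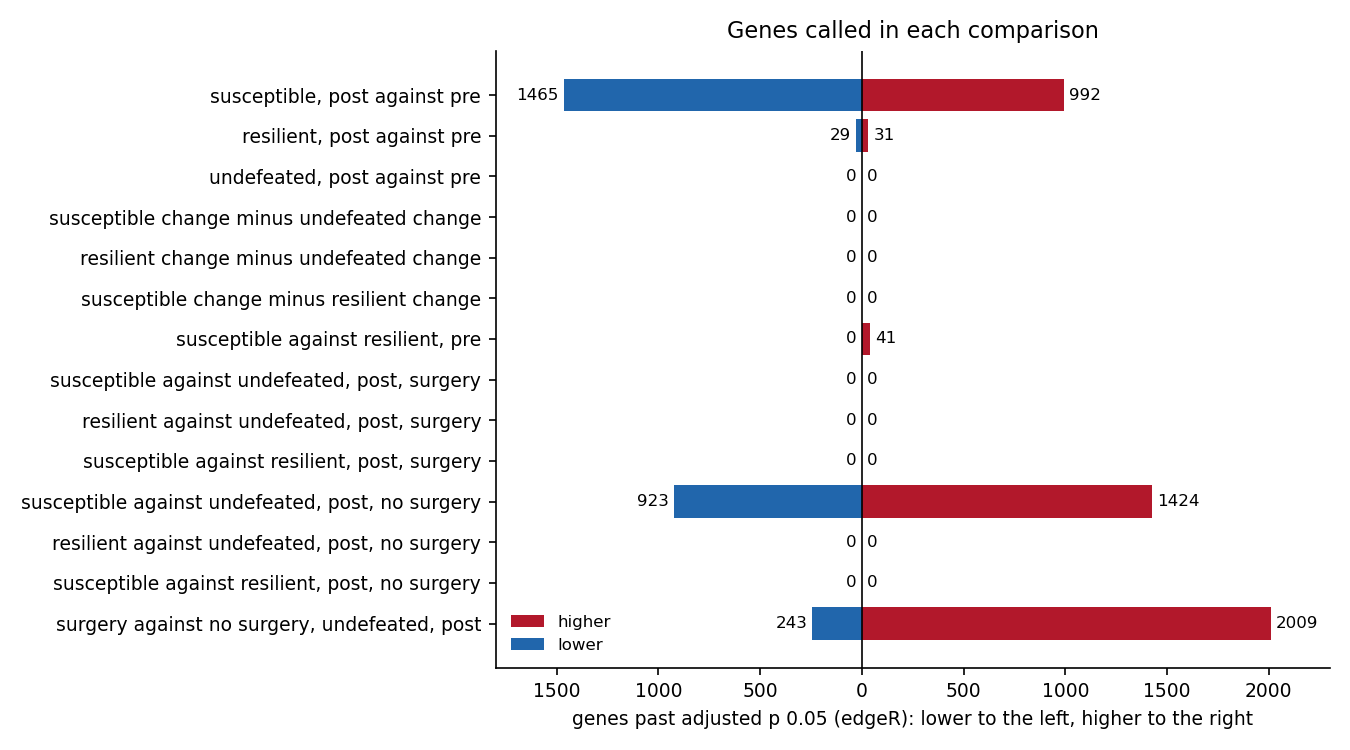
Number of genes past an adjusted p of 0.05 (edgeR) in each of the 14 comparisons, with genes called lower drawn to the left of 0 and genes called higher to the right. Susceptible mice post against pre had 992 genes higher and 1465 lower, and resilient mice 31 and 29.

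The post against pre comparison in susceptible mice addresses how the sperm RNA of the same animals changed across the defeat period. Several genes known from macrophages and acute inflammation were among those that rose most. Saa3, an acute-phase serum amyloid (ENSMUSG00000040026, GRCm38 chromosome 7, 46711998 to 46715700), went from 0.357 ± 0.269 to 220 ± 214 CPM (SD, n = 7 each). It was higher in 7 of 7 mice, with a log2 change of 9.26 ± 1.73 (SE, edgeR adjusted p = 0.00403). Alox15, a lipoxygenase of resident macrophages (ENSMUSG00000018924, chromosome 11, 70344152 to 70352031), went from 1.22 ± 0.676 to 216 ± 158 CPM, a log2 change of 7.44 ± 1.44 (edgeR adjusted p = 0.00478). The chemokine Ccl24 rose by 6.87 ± 1.43 (log2 ± SE), the chemokine Cxcl13 by 6.76 ± 1.44 and the macrophage complement receptor Vsig4 by 6.46 ± 1.28. So did Serpinb2 (8.77 ± 1.63) and the lubricating glycoprotein Prg4 (7.16 ± 1.48), whose spans overlap other genes and whose counts are uncertain for that reason. Red blood cell genes were among those that fell most. The erythrocyte anion exchanger Slc4a1 (ENSMUSG00000006574, chromosome 11, 102348824 to 102366203) went from 86.3 ± 107 to 1.83 ± 0.791 CPM, a log2 change of −5.56 ± 0.89 (edgeR adjusted p = 0.00203). Epb42, a protein of the red cell membrane, changed by −5.65 ± 1.05. In all, 2457 of 21106 genes were called, 992 higher and 1465 lower, against 7256 at an unadjusted p under 0.05.

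Among the lists of other cell types, all 8 tested red blood cell genes fell (median log2 change −5.05). The level of the list was lower in 7 of 7 mice, at 4.27 ± 0.52 post and 7.55 ± 2.18 pre (mean log2(CPM + 1) ± SD, exact p = 0.0156, the smallest that 7 mice allow, adjusted 0.0365). Of 25 leukocyte genes 9 rose, 2 fell and 14 did not pass (adjusted over the list alone, 17 and 2). The monocyte receptor Cd14 rose by 4.36 ± 1.22 and the macrophage lysozyme Lyz2 by 3.41 ± 1.08, from 134 ± 150 to 1423 ± 881 CPM, whereas the neutrophil gene S100a9 changed by −5.06 ± 1.29. The neutrophil chemokine receptor Cxcr2, outside that list, changed by −5.61 ± 1.34. The leukocyte level was higher in 7 of 7 mice (6.54 ± 0.69 post, 4.22 ± 1.42 pre, exact p = 0.0156, adjusted 0.0365). So was the endothelial level (2.75 ± 0.28 and 2.13 ± 0.30, exact p = 0.0156, adjusted 0.0365). Of 14 endothelial genes 3 rose, among them Pecam1 (3.08 ± 1.04), and Vwf fell by 0.96 ± 0.28. Of 26 smooth muscle and connective tissue genes 2 rose (Tagln, 1.80, and Fn1, 5.52 ± 1.23, whose span overlaps another gene) and Mylk fell by 1.41, with 4 and 1 adjusted over the list alone. Of 7 seminal vesicle and prostate genes Crym rose (2.46 ± 0.63), and of 14 fat cell genes none was called. Camera gave adjusted p = 2.09e-07 for the red blood cell list and 2.91e-08 for the leukocyte list, but adjusted p = 0.355 and p = 0.502 with an estimated correlation. For the endothelial and smooth muscle lists these were 0.0302 and 0.00442, and adjusted p = 0.502 and p = 0.517 with an estimated correlation.

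Members of the germ cell lists fell beside these changes, unevenly between mice. Of 21 acrosome and round spermatid genes 7 fell (adjusted over the list alone, 14; median −2.03). Of 36 late spermatid and sperm genes 4 fell (4; median −0.71), of 28 meiotic genes 2 fell (13; median −1.68), and no member of these lists rose. The sperm calcium channel subunits Catsper3 and Catsper4 fell by 2.90 ± 0.80 and 2.35 ± 0.67, and the acrosomal membrane protein Spaca1 by 3.35 ± 0.97. Izumo1, the sperm receptor for egg fusion, changed by −3.17 ± 0.85, with a span that overlaps other genes. The level of the late spermatid list was lower in 6 of 7 mice and that of the acrosome and meiotic lists in 5 of 7 (exact p = 0.234, 0.156 and 0.172). The summed CPM of meiotic genes went from 5134, 3762 and 3841 to 615, 421 and 72 in mice 28, 52 and 57, and rose from 312 to 2081 in mouse 11 and from 680 to 990 in mouse 51. Without mouse 28, 52 or 57 no member of the 3 lists was called, also when adjusted over the list alone (acrosome median −1.54, −1.62 and −1.61). Without mouse 42 none passed over all genes, and without mouse 27 only 3 late spermatid genes did, but adjusted over the list alone 10 acrosome and 3 late spermatid genes fell without either (acrosome median −2.04 and −1.90) and no meiotic gene passed (median −1.70 and −1.74). Without mouse 11, 19 acrosome, 25 late spermatid and 19 meiotic genes fell. In mouse 57 post 46.6% of counts lay in ribosomal RNA genes. Camera gave adjusted p = 4.61e-06 to 7.76e-05 for these 3 lists, and adjusted p = 0.502 for each with an estimated correlation. Of 38 epididymal genes 16 fell (median −2.16, but 0.16 with DESeq2), with Crisp4 at −4.54 ± 0.94 in 7 of 7 mice. Mouse 11 had a pre level of 7.96 in that list, against 4.0 in the next mouse, and without it 1 of 37 epididymal genes fell and 2 rose (median 0.72). Lcn2, called at −2.72 ± 0.87, was lower in only 1 of 7 mice and the ribonuclease homologue Rnase10, called at −6.45 ± 1.39, in 3 of 7. Camera gave no call for the epididymal list (adjusted p = 0.274).

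Of 23 immediate early and heat shock genes 9 rose and none fell (17 adjusted over the list alone, median 1.77). The nuclear receptor Nr4a1 went from 44.4 ± 30.7 to 366 ± 172 CPM (3.05 ± 0.83), with Ier3 at 2.67 ± 0.73 and Fosb at 2.46 ± 0.70. The level of the list was 6.24 ± 0.27 post and 4.39 ± 0.73 pre and was higher in 7 of 7 mice (exact p = 0.0156, adjusted 0.0547). Of 20 glucocorticoid responsive genes 3 rose, among them the NF-kappa-B inhibitor Nfkbia (2.92 ± 0.75) and the cell cycle inhibitor Cdkn1a (1.97 ± 0.49). Lcn2 was called lower by edgeR, but was lower in few of the mice, as given above. Without mouse 11, 6 genes of this list rose and none fell. Camera gave adjusted p = 8.74e-10 for immediate early genes and 3.05e-05 for glucocorticoid genes, and adjusted p = 0.355 and p = 0.502 with an estimated correlation. The 76 ribosomal protein genes had a median of 0.80 (camera adjusted p = 1.86e-11). Of 25 interferon genes the antiviral Rsad2 fell by 4.27 ± 1.14 while the list's median was 0.92, and of 25 methylation enzymes Dnmt3l changed by −2.25 ± 0.67, with a span that overlaps other genes. Camera gave the interferon and methylation lists adjusted p = 0.000168 and 0.0302, and with an estimated correlation the ribosomal, interferon and methylation lists had adjusted p = 0.502 each. None of the 13 mitochondrially encoded genes (median 0.68, camera adjusted p = 0.0462, adjusted p = 0.59 with an estimated correlation) or of the 77 respiratory chain genes (median 0.13, −0.02 with RLE factors, camera adjusted p = 0.192) was called. Long noncoding RNAs made up 19.7% of the called genes and 15.3% of those tested (odds ratio 1.45, Fisher's exact adjusted p = 1.26e-10). Of the 483 called, 425 were lower. This p takes genes as independent and does not measure evidence over mice.

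DESeq2 called 1547 genes higher and 3570 lower (30.2% higher, against 40.4% by edgeR), the mouse as a replicate block left 451 (380 higher and 71 lower, so 84.3% higher, 433 of them among the 2457), the scores of 4 cell lists as covariates left 211 (39 higher and 172 lower, 7 among the 2457), and leaving out libraries with over 50% of counts in 10 genes left 942 (421 higher and 521 lower, median size of the 2457 changes 2.46, against 2.50 with them). More genes were higher than lower with only these groups in the fit (1401 and 1126), with the other cell score (990 and 771) and without mouse 52 (475 and 374). Without mouse 11 the count was 7160, without mouse 27 it was 1148, without 28 it was 426, without 42 it was 470, without 52 it was 849 and without 57 it was 513.

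**Figure D2:**
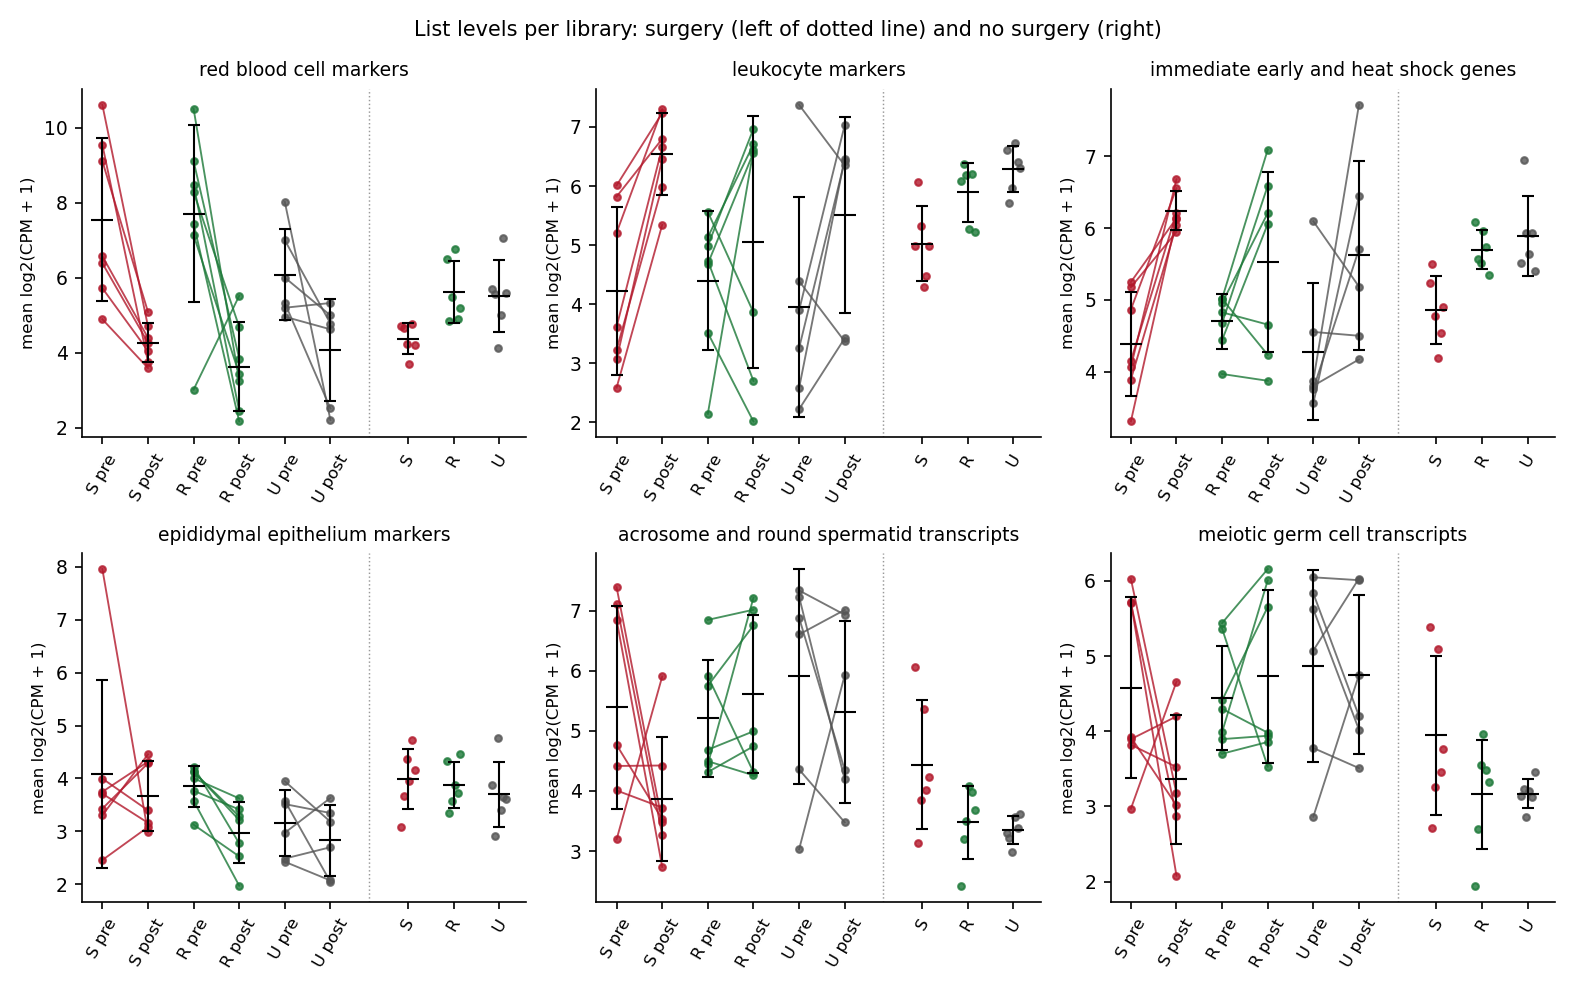
Level of 6 gene lists in each library (mean log2(CPM + 1) of the list's genes), with S, R and U for susceptible, resilient and undefeated mice, lines joining the pre and post libraries of a mouse, and bars for the mean ± SD of each group. In susceptible mice the red blood cell level fell from 7.55 to 4.27 and the leukocyte level rose from 4.22 to 6.54, each in 7 of 7 mice.

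In resilient mice the same comparison called 31 genes higher and 29 lower, with 2852 at an unadjusted p under 0.05. Red blood cell genes fell. The beta globin Hbb-bs went from 9119 ± 8408 to 316 ± 391 CPM (−4.85 ± 1.06, SE, n = 7 each, edgeR adjusted p = 0.0295) and Slc4a1 from 98.2 ± 158 to 2.47 ± 0.982 (−5.32 ± 0.88). The erythroid ubiquitin ligase Trim10 changed by −6.43 ± 1.07, in 6 of 7 mice. All 8 tested red blood cell genes fell, some of them near-identical globin copies between which reads are hard to assign. The level of the list was 3.62 ± 1.19 post and 7.71 ± 2.35 pre, lower in 6 of 7 mice (exact p = 0.0312, adjusted 0.109). It kept its camera call with an estimated correlation (adjusted p = 0.0267, and 0.117 with the mouse as a block). Saa3 rose from 0.807 ± 0.555 to 192 ± 190 CPM (7.99 ± 1.64), Alox15 by 6.77 ± 1.40, the macrophage arginase Arg1 by 5.43 ± 1.18, and the overlapping genes Serpinb2 and Prg4 by 6.88 ± 1.51 and 6.53 ± 1.45. No member of the leukocyte list passed over all genes, but adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.0174, adjusted p = 0.866 with an estimated correlation). In the same way 7 of 23 immediate early genes rose (0.000126, adjusted p = 0.696 with an estimated correlation). The epididymal list had a median of −1.18 with no member called (camera adjusted p = 3.76e-05, adjusted p = 0.696 with an estimated correlation). Its level was 2.97 post and 3.85 pre, lower in 7 of 7 mice (exact p = 0.0156, adjusted 0.109). The calls ended with the mouse as a replicate block (0 by edgeR, with 2409 at an unadjusted p under 0.05), and the count was 903 by DESeq2, 126 with RLE factors, 118 with only these groups in the fit, 639 with the other cell score and 245 with the scores of 4 cell lists (47 higher and 198 lower). It was 33 without mouse 47, 13 without 48, 2 without 49 and 0 without 55 (by edgeR, with 1698 at an unadjusted p under 0.05).

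In undefeated mice, which show the change between collections without defeat, edgeR called 0 genes, with 1134 at an unadjusted p under 0.05, and DESeq2 called 40. The smallest adjusted p was 0.101, for the lysosomal protease gene Ctsl (3.15 ± 0.65, SE, higher in 6 of 6 mice, but 1.32 without mouse 61). It was the same for Spp1 (osteopontin, 8.41 ± 1.72, 400 ± 972 against 1.16 ± 0.942 CPM, n = 6 each), for Syngr1 (4.01 ± 0.82) and, on the lower side, for Tmem108 (−2.23 ± 0.46), followed by Gm29050 (−1.80, adjusted 0.432). The changes of Spp1 and Syngr1 rested on mouse 61, whose post library had 2383 CPM of Spp1 against 0.291 to 5.56 in the other 5. Without it they were 1.70 and 0.97, with Tmem108 at −1.56 and Gm29050 at −2.03 (adjusted 0.0443). The spans of all 5 genes overlap other genes. Adjusted over the list alone, 7 of 8 red blood cell genes fell (median −2.25, level 4.08 ± 1.35 post and 6.09 ± 1.20 pre, lower in 5 of 6 mice, exact p = 0.0625, adjusted 0.365), and 9 of 14 fat cell genes rose (2.85). The rise of fat cell genes rested on mouse 69, whose post library had a summed CPM of 3465 for these genes, against 1623 in mouse 61 and 186 to 250 in the other 4. Without mouse 69 none passed in the list alone (median 0.29). In the same way 8 of 23 immediate early genes (1.07), 2 leukocyte genes (0.58), 3 endothelial genes and 1 glucocorticoid gene rose. Camera gave adjusted p = 6.53e-18 for the immediate early list, 3.75e-14 for leukocytes, 1.57e-08 for red blood cells and 0.00293 for fat cells (unadjusted p = 0.0746 without mouse 69). With an estimated correlation these were adjusted p = 0.075, p = 0.225, p = 0.161 and p = 0.408. Without mouse 61, whose 2 samples have contradictory time points in the title and the file name, 259 genes were higher and 4 lower. The count was also 120 with the other cell score (18 higher and 102 lower) and 1420 with the scores of 4 cell lists (408 and 1012).

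Whether defeat status altered the change was tested on the difference of the changes. No gene passed by edgeR for susceptible minus undefeated (2178 at an unadjusted p under 0.05, DESeq2 28), resilient minus undefeated (991, DESeq2 1) or susceptible minus resilient mice (4266, DESeq2 18 higher and 704 lower). The smallest edgeR adjusted p for susceptible minus undefeated was 0.304, with the immunoglobulin genes Igha (10.77 ± 2.25) and Jchain (5.40 ± 1.20) and, on the lower side, Mfge8 (−8.16 ± 1.76). These were 2.06, 2.45 and −5.36 without mouse 61, whose pre library had 287 CPM of Igha against 0 to 0.378 in the other 5 undefeated pre libraries. For susceptible minus resilient it was 0.18, with Inhbb, an inhibin subunit, at −6.28 ± 1.42 and the growth factor binding protein Igfbp2 at 3.15 ± 0.87. For resilient minus undefeated it was 0.837, with Jchain at 4.89 and Igha at 8.23 (1.93 and −0.41 without mouse 61). Adjusted over the list alone, 13 of 21 acrosome genes (median −2.67), 13 meiotic genes (−2.31) and 3 late spermatid genes had a lower change in susceptible than in resilient mice. Of the epididymal genes 11 had a lower and 1 a higher change (list median −1.04, but 1.30 with DESeq2). In susceptible minus undefeated mice, 14 epididymal genes (median −1.54, but 0.70 with DESeq2) and 4 red blood cell genes were lower, and in resilient minus undefeated mice 3 fat cell genes (none without mouse 69) and 1 red blood cell gene. The lower epididymal values rested on mouse 11, whose pre level of 7.96 stood apart. Without it no epididymal gene was lower in the list alone in either difference (medians 1.93 against resilient and 1.13 against undefeated mice). Without mouse 11, 2850 genes were called for susceptible minus resilient mice (293 higher and 2557 lower). No gene was called in these 3 differences with any other mouse left out. With an estimated correlation no list was called in these differences (adjusted p of at least 0.825, 0.482 and 0.52 in the order susceptible minus undefeated, resilient minus undefeated and susceptible minus resilient). The glucocorticoid level changed by 1.23 more and the ribosomal protein level by 1.30 more in susceptible than in resilient mice (exact p = 0.021 and 0.0239, both adjusted 0.0836).

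**Figure D3:**
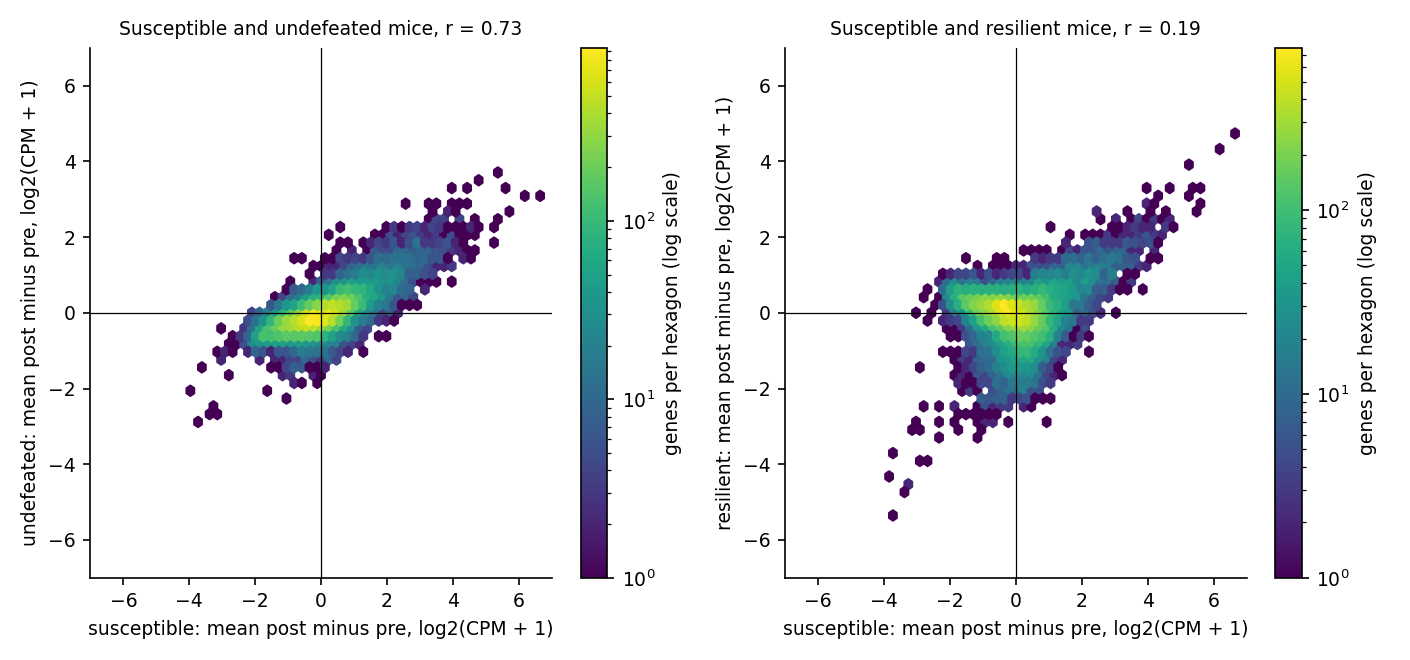
Mean change post minus pre of each of 21106 genes in log2(CPM + 1), in susceptible mice on the horizontal axis and in resilient or undefeated mice on the vertical axis, with colour for the number of genes per hexagon on a log scale. The change of susceptible mice correlated at r = 0.73 with that of undefeated mice and at r = 0.19 with that of resilient mice.

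The whole profile moved by a root mean square of 0.902 log2 units in susceptible mice, 0.587 in resilient and 0.460 in undefeated mice. Without mouse 61 the undefeated shift was 0.6998 (exact p = 0.188, smallest possible 0.0625), above that of resilient mice. With all mice none of these passed the sign-flip test (exact p = 0.0781, 0.141 and 0.406, against smallest possible values of 0.0156, 0.0156 and 0.0312). Without mouse 11 the susceptible shift was 1.09 (exact p = 0.0312), and without mouse 54 the resilient shift was 0.724 (exact p = 0.0312). Across genes, which are not independent, the susceptible change correlated with the undefeated change at Pearson r = 0.73 and Spearman rho = 0.64. This r was above that of every other flip of mice (highest 0.717, exact p = 0.0156 for both, adjusted 0.0781 over 5 correlations). Among genes with a mean CPM of at least 10 it was not, at r = 0.766 against 0.774 for the highest other flip (exact p = 0.0312). In all, 74.0% of genes had the same sign. The susceptible and resilient changes had r = 0.19 and rho = −0.05 (exact p = 0.719 and 0.953), and the resilient and undefeated changes r = 0.41 and rho = 0.13 (exact p = 0.453 and 0.812).

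Before defeat, susceptible and resilient mice differed in 41 genes, all higher in mice later classed as susceptible, and epididymal genes led. These were the lipocalins Lcn10 (9.54 ± 2.03, SE, 96.8 ± 255 against 0.225 ± 0.513 CPM, n = 7 each) and Lcn5 (8.49 ± 1.79) and the metalloprotease Adam28 (9.15 ± 1.92), each at edgeR adjusted p = 0.0346. Of 38 epididymal genes 9 were higher (adjusted over the list alone, 16; median 0.87, −0.21 with DESeq2; camera adjusted p = 0.313). These levels came from mouse 11, whose epididymal level was 7.96 against 4.0 in the next mouse of its group. DESeq2 called 19, and 518 genes had an unadjusted p under 0.05. By edgeR 0 genes were called with only these groups in the fit (404 at an unadjusted p under 0.05), with the scores of 4 cell lists (1395) or without libraries with over 50% of counts in 10 genes (423). The count was also 0 without mouse 11 (225), 39 (518), 47 (856), 48 (417), 49 (431), 54 (706) or 55 (479), and 9 without mouse 59.

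After defeat in the surgery cohort, the comparison of classes addresses how sperm RNA differed between classes of mice that shared the surgery. No gene passed by edgeR for susceptible against undefeated mice (4871 at an unadjusted p under 0.05, DESeq2 13 higher and 583 lower), resilient against undefeated mice (166, DESeq2 0) or susceptible against resilient mice (5023, DESeq2 61 higher and 2330 lower). The smallest adjusted p for susceptible against undefeated mice was 0.202, with the thyroid hormone deiodinase Dio2 at −4.49 ± 0.91 (−1.55 without mouse 61), Spp1 at −7.02 ± 1.51 (0.14 without mouse 61) and Ifrd2 at 0.90 ± 0.20. For resilient against undefeated mice it was 0.75, with the bone-resorbing protease gene Ctsk at −4.12 ± 0.92 (−0.56 without mouse 61), and for susceptible against resilient mice 0.109, with Igfbp2 at 2.40 ± 0.63 and Mageb18 at −4.97 ± 1.18. Without mouse 11, 3218 genes were called against undefeated mice (469 higher and 2749 lower) and 4153 against resilient mice (418 and 3735). With any other mouse left out the counts were 0, except 2 against undefeated mice without mouse 67. Adjusted over the list alone, 17 of 28 meiotic genes were lower in susceptible than in undefeated mice (median −1.81, camera adjusted p = 2.98e-09, adjusted p = 0.703 with an estimated correlation). So were 4 fat cell genes (none without mouse 69) and 1 glucocorticoid gene. Undefeated mice 66 and 68 stood apart in summed meiotic CPM, as given below for surgery against no surgery. Their leukocyte levels were 3.42 and 3.37, against 6.35 or more in the other undefeated mice. In resilient against undefeated mice 10 of 14 fat cell genes were lower (median −2.86, camera adjusted p = 1.43e-09, adjusted p = 0.103 with an estimated correlation). This rested on mouse 69, with 3465 summed CPM of fat cell genes against 155 to 265 in resilient mice. Without it none was lower in the list alone (median 0.0252, camera unadjusted p = 0.22). Against resilient mice, susceptible mice had 17 meiotic, 12 acrosome and 4 late spermatid genes lower in the list alone (adjusted p of at least 0.479 with an estimated correlation). The levels of these lists differed by −1.37, −1.75 and −1.11 (exact p = 0.0303, 0.0245 and 0.0286, each adjusted 0.0303). With each mouse left out alone the meiotic difference ran from −1.59 to −1.13 (exact p from 0.0152 to 0.0618). The acrosome difference ran from −2.09 to −1.48 (exact p from 0.00466 to 0.0466) and the late spermatid difference from −1.38 to −0.75 (exact p from 0.00408 to 0.0635). Resilient mice 39, 47 and 59 stood apart, with summed meiotic CPM of 3612, 5576 and 5078 against 266 to 1037 in the other 4. Their summed leukocyte CPM was 956, 214 and 816, against 2619 to 11492. The leukocyte level was higher by 1.48 in susceptible than in resilient mice (exact p = 0.125, adjusted 0.162). The smooth muscle and endothelial levels were higher by 1.07 and 0.41 (adjusted 0.0449).

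**Figure D4:**
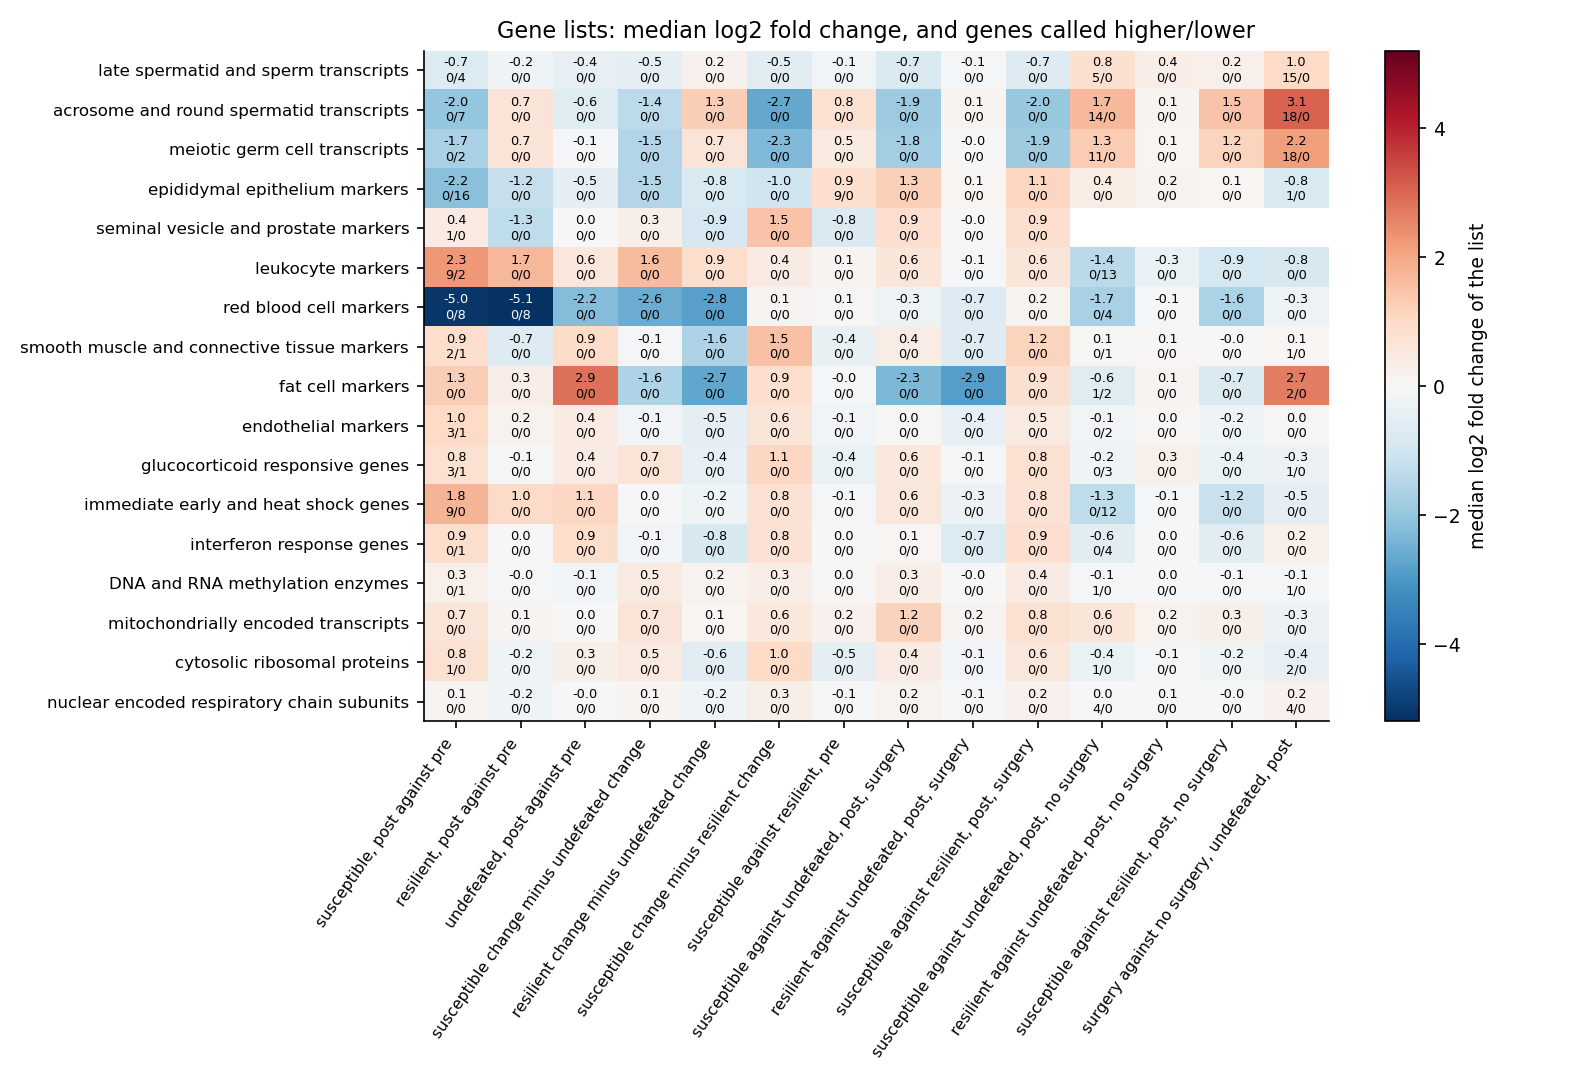
Median log2 fold change of each of the 17 lists in each comparison, as colour, with the numbers of members called higher and lower printed in the cells. In mice without surgery, susceptible against undefeated, 14 acrosome genes were higher and 13 leukocyte genes were lower.

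In mice without surgery, susceptible and undefeated mice differed in 2347 of 17046 genes, 1424 higher and 923 lower in susceptible mice (5610 at an unadjusted p under 0.05). Genes expressed in germ cells were among the higher ones. Examples were the sperm hyaluronidase Hyal6 (4.18 ± 0.91, SE, 26.2 ± 37.9 against 1.4 ± 0.9 CPM, n = 6 each, edgeR adjusted p = 0.0174), Cox7b2 (4.11 ± 0.79) and the testis protease Prss42 (3.95 ± 0.90). Others were the zona-binding protein Zpbp2 (3.80 ± 0.83) and the sperm lactate dehydrogenase Ldhc (2.42 ± 0.65, 398 ± 469 against 74.1 ± 21.7 CPM). Macrophage and neutrophil genes were among the lower ones, with Arg1 at −2.81 ± 0.49 (2.67 ± 1.51 against 17.8 ± 8.27 CPM, edgeR adjusted p = 0.00747). Also lower were Ccl24 at −2.96 ± 0.64, the neutrophil deiminase Padi4 at −2.90 ± 0.47 and Lyz2 at −2.18 ± 0.41 (285 ± 133 against 1289 ± 537 CPM). The aldo-keto reductase gene Akr1b7 was lower as well (−4.36 ± 0.91, 23 ± 16.5 against 471 ± 295 CPM), with a span that overlaps another gene.

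By list in that comparison, 14 of 21 acrosome genes were higher (18 adjusted over the list alone, median 1.70). So were 11 of 27 meiotic genes (14, 1.31), with Mael at 3.09 ± 0.72 and Stag3 at 2.64 ± 0.66. So were 5 of 35 late spermatid genes (10, 0.81), and none of these was lower. Of 25 leukocyte genes 13 were lower (20 adjusted over the list alone, median −1.38), with the immune signalling adaptors Tyrobp at −1.92 ± 0.29 and Fcer1g at −1.78 ± 0.31. Of 23 immediate early genes 12 were lower (15, −1.34), with Ier3 at −2.04 ± 0.40. Of 6 red blood cell genes 4 were lower (5, −1.68), of 24 interferon genes 4 (6, −0.57), and of 20 glucocorticoid genes 3 (3, −0.21). The leukocyte level was 5.02 ± 0.64 in susceptible and 6.29 ± 0.39 in undefeated mice (exact p = 0.00649, adjusted 0.0455), and the immediate early level differed by −1.04 (exact p = 0.00433, adjusted 0.0303). Smaller counts were 1 lower for smooth muscle, 1 higher and 2 lower for fat cells, and 2 lower for endothelium. They were 1 higher for methylation enzymes, 1 higher of 76 ribosomal protein genes, 4 higher of 75 respiratory chain genes, and 0 for the 29 epididymal and 11 mitochondrially encoded genes. Camera gave adjusted p = 3.06e-13 for leukocytes, 2.67e-08 for immediate early genes and 2.57e-06 for acrosome genes. With an estimated correlation these were adjusted p = 0.282, p = 0.174 and p = 0.545. For the meiotic, late spermatid, interferon and red blood cell lists it gave 0.000359, 0.00477, 0.000222 and 0.00162, and with an estimated correlation adjusted p of at least 0.545. The count was 4141 by DESeq2, 179 with the other cell score (13 higher and 166 lower), 1765 without libraries with over 50% of counts in 10 genes (749 higher and 1016 lower), 0 by edgeR with the scores of 4 cell lists (1026 at an unadjusted p under 0.05) and 1431 without the 4 mice titled ER or D, all of them susceptible. Of these 1431, 1371 were higher and 60 lower, and of 25 leukocyte genes 1 was higher and 1 lower (list median −0.93). The count was 496 without mouse 86 (162 higher and 334 lower) and 125 without D37 (14 higher and 111 lower). These 2 mice had summed meiotic CPM of 2895 and 2797, against 182 to 1014 in the other susceptible mice. Without 86 only 2 members of the 3 germ cell lists were called, and without D37 none was. Adjusted over the list alone, 14 acrosome and 7 meiotic genes were still higher without 86 (medians 1.14 and 0.87, 1 acrosome gene lower) and 16 and 11 without D37 (medians 1.53 and 1.07). No late spermatid gene passed without either (medians 0.56 and 0.75). The count was 4834 without 89, 837 without 93, 890 without 96 (427 higher and 463 lower), 1409 without 98 and 927 without 100.

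No gene passed by edgeR for resilient against undefeated mice without surgery (380 at an unadjusted p under 0.05, DESeq2 0). Flnc (0.88 ± 0.23) and Wfdc17 (−1.45 ± 0.32), among the smallest p, had an edgeR adjusted p of 1, and no list member passed (adjusted p of at least 0.905 with an estimated correlation). Susceptible against resilient mice gave 0 genes by edgeR as well (4206 at an unadjusted p under 0.05), but 2203 by DESeq2. There were 1972 without libraries with over 50% of counts in 10 genes, 922 without the mice titled ER or D and 1 without a filter on low counts. With 1 mouse left out there were 3340 without 89 (2066 higher and 1274 lower), 836 without D33, 443 without ER20, 10 without 90, 4 without 88 and 0 otherwise. Its smallest adjusted p was 0.0612, with the prostaglandin synthase Ptgs2 at −3.14 ± 0.50 and the splicing factor Prpf40b at 1.08 ± 0.19. Adjusted over the list alone, 15 acrosome and 14 meiotic genes were higher and 12 leukocyte, 12 immediate early, 5 red blood cell and 3 interferon genes were lower (adjusted p of at least 0.158 with an estimated correlation). The red blood cell level differed by −1.24 (exact p = 0.00216, adjusted 0.0152) and the immediate early level by −0.84 (exact p = 0.00433, adjusted 0.0303).

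Between cohorts, the differences of susceptible from undefeated mice correlated across genes at r = −0.65 and rho = −0.61 (permutation p = 0.31 and 0.35 over 100 groupings, r = −0.64 without mouse 61). Those of resilient from undefeated mice correlated at r = 0.03 and rho = 0.02 (permutation p = 0.79 and 0.83). Undefeated mice with surgery had 2009 genes higher and 243 lower than undefeated mice without surgery (of 16572, 5437 at an unadjusted p under 0.05). Surgery cannot be told apart from cohort here. The cohorts hold different mice, only mice with surgery gave an earlier sample, and the read configuration of each library is not stated. Germ cell genes were among the higher ones. They included the testis histone Hist1h2ba (5.58 ± 1.30, SE, 80.4 ± 112 against 1.61 ± 0.814 CPM, n = 6 each, edgeR adjusted p = 0.0379), Cox7b2 (5.19 ± 1.16), the sperm tail anchoring protein Akap3 (3.73 ± 0.85) and Ldhc (3.01 ± 0.73). Of 21 acrosome genes 18 were higher (19 adjusted over the list alone, median 3.09), of 27 meiotic genes 18 (23, 2.17) and of 36 late spermatid genes 15 (19, 1.04). Surgery mice 66 and 68 stood apart, with summed meiotic CPM of 5290 and 5318 against 718 to 1775 in the other 4, and summed leukocyte CPM of 693 and 659 against 5177 to 10326. Without 66 or 68 no member of these lists was called over all genes. Adjusted over the list alone, 19 acrosome and 20 meiotic genes were higher without either (medians 2.71 and 1.90 without 66, 2.61 and 1.85 without 68). The leukocyte level differed by −1.11 (exact p = 0.117, adjusted 0.586), with no member called (median −0.85). Camera gave adjusted p = 7.78e-06, 1.56e-07 and 5.21e-05, and adjusted p = 0.796 for each with an estimated correlation. Gm19951 and Tmtc2 were lower (−5.81 ± 1.53 and −4.30 ± 1.06), with 20124 ± 25897 and 1671 ± 1996 CPM without surgery. The 10 most counted genes took 16.5 ± 10.2% of counts with and 41.4 ± 29.0% without surgery (exact p = 0.0974). The number of genes detected was 25345 against 21648 (exact p = 0.00216, adjusted 0.013). Long noncoding RNAs were more frequent among the calls (odds ratio 1.96, Fisher's exact adjusted p = 1.33e-20, 311 higher and 18 lower). Here too the p takes genes as independent and does not measure evidence over mice. By edgeR 0 genes were called with the scores of 4 cell lists (868 at an unadjusted p under 0.05), without libraries with over 50% of counts in 10 genes (3838), and without mouse 61, 66, 68, 91, 92, 93, 96, 98 or 100, each left out alone (4052 to 5340). DESeq2 called 5247, and the count without mouse 67 was 4529.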

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

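The macrophage list, the correlation of the susceptible with the undefeated change as a test, the sizes of called genes without libraries dominated by a few genes or without mice titled ER or D, each susceptible mouse alone, the macrophage level of mouse 61, and the differences between cohorts were tests chosen after the results were seen.

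Genes higher in susceptible post libraries included many of macrophages, so a list of 18 markers of large peritoneal macrophages was written from knowledge of these cells and then tested (the labels name no step that sorts out such cells). Its members Itga6 and Naip1 had been seen before among the leading genes of the comparison of susceptible with undefeated mice without surgery, although the prediction recorded before the test stated that no member had been seen. Of 17 tested members, each at 1 CPM or more in the mean of all pre libraries and none of them in another list, 8 rose and none fell (11 adjusted over the list alone, median log2 change 2.36, camera p = 0.0228 with an estimated correlation) at a level of 5.2 ± 0.775 post and 3.12 ± 0.447 pre, which was higher in 7 of 7 mice (exact p = 0.0156, adjusted 0.0547 over 14 comparisons). Timd4 and Icam2 reached 1 CPM only through the pre library of mouse 61 (means of 0.554 and 0.745 CPM without it), and without these 2 members 6 of 15 rose (8 adjusted over the list alone, median 1.51, camera p = 0.0244 with an estimated correlation, exact p = 0.0156 of the level). The camera p-values of the macrophage list, here and below, are unadjusted. Macrophage genes of this same comparison prompted the list, so its rise here is not independent support. RNA from such cells is a candidate source for these genes. Its abundant markers reached 202 ± 132 CPM (Ltbp1, overlapping another gene), 175 ± 117 CPM (F5, also overlapping) and 84.1 ± 61.2 CPM (F10). The leukocyte level was also higher in 7 of 7 mice, so these values do not tell such cells apart from other leukocytes. A change between the collections that undefeated mice share is also open, with r = 0.73 across genes between both changes (0.89 without mouse 61, and 0.766 at a mean CPM of at least 10, where another flip of mice reached 0.774). A few genes taking most of the counts is argued against as the whole cause. Without those libraries the genes called higher had a median change of 2.28 (2.42 with them, SE 0.697 and 0.692), and 990 of 990 kept their direction. In the smaller set of samples 417 of the 992 calls were kept. These genes were called in a fit that held the remaining libraries too, which favours a kept size. An effect of defeat stays open, and these values do not test it. The difference of the susceptible and undefeated changes had 0 genes by edgeR, also with each mouse left out, which does not exclude such an effect.

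Mouse 61 moved against the other undefeated mice: across genes its post minus pre change correlated at r = −0.61 with the mean change of the other mice, against 0.02 to 0.82 for the other undefeated mice and −0.35 for the lowest of all other mice. Exchanged time points of its samples may account for this, as its file names also give the reverse of its titles, and its macrophage marker level was 5.51 in the sample titled pre (highest other pre 3.77) and 3.96 in the sample titled post. Other values do not follow an exchange. Its red blood cell level changed by 0.13, outside the −5.81 to −0.34 of the other undefeated mice in either order. Spp1 had 2383 CPM in the sample titled post, against 0.0552 to 5.56 in the other undefeated mice, pre and post. Its leukocyte change of −1.03 speaks for neither order. It had its like in mouse 68 (−1.02), and turned round it would lie within the −1.02 to 3.89 of the other undefeated mice. More RNA of large peritoneal macrophages in the library titled post is argued against. By the titles the macrophage marker level changed by −1.54 from pre to post, against 0.0257 to 2.59 in the other undefeated mice. If the time points are exchanged, the change has the opposite sign and lies within that range, so the argument holds only for the titled order. More fat RNA in that library cannot be told apart from other explanations, because its fat cell level, 3.24, lay between the median of 2.90 and the highest of 6.86 of the others. The titles were kept for all results, and no biological explanation was tested.

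Susceptible and undefeated mice without surgery differed in 2347 genes, and the macrophage list pointed the other way there: without Itga6 and Naip1, 15 of 15 members had values below 0, 9 of them called lower (14 adjusted over the list alone, median −1.47, camera p = 0.00457 with an estimated correlation), at a level of 3.55 ± 0.34 against 4.90 ± 0.37 (exact p = 0.00216, adjusted 0.0303). Less RNA from such cells in susceptible mice may contribute to the lower genes. The leukocyte list, which shares no member with this list, had a level difference of −1.26 there, against −1.35 for the macrophage list. These values therefore do not tell such cells apart from other leukocytes. A few genes taking most of the counts is argued against as the whole cause, since without those libraries the called genes had a median size of 1.76 (1.58 with them, SE 0.508 and 0.429). Here too the genes were called in a fit that held the remaining libraries, which favours a kept size. A difference between mice titled AMC and mice titled ER or D cannot be told apart from class, since all 4 mice titled ER or D were susceptible and only 86 and 89 were left. Without the 4 mice the higher genes had a median of 2.34 (1.89 with them, SE 0.60 and 0.535, 1021 of 1424 calls kept), but mouse 86 alone differed from undefeated mice by a median of 2.75 and mouse 89 by −0.000659 (log2(CPM + 1)). The lower genes had a median of −0.93 (−1.29 with them, SE 0.477 and 0.349, 43 of 923 calls kept), with −1.25 in mouse 86 and −0.41 in mouse 89. A difference due to defeat remains open, and these values do not test it. Resilient mice, also defeated, differed from undefeated mice in 0 genes by edgeR, which does not settle it for susceptible mice.

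Other splits of the same samples were fitted in the same way. Where pre and post samples were compared, each split exchanged the time points within mice. For susceptible mice 9 of the 64 such splits gave as many genes as the real 2457 (highest other 8133), so chance cannot be excluded, whereas of 36 splits that kept the samples of a mouse together 1 gave as many (highest 3177). For resilient mice only the real split of 64 reached 60 genes (1 of 64, highest other 34). This makes chance unlikely but does not exclude it, since shares of splits were not adjusted over the comparisons. The calls also ended with the mouse as a replicate block. For susceptible against undefeated mice without surgery 3 of 100 splits reached 2347 genes, the real one included (highest other 4982). For surgery against no surgery 1 of 100 reached 2252 (highest other 1412). Chance is unlikely for both but not excluded, for the same reason. The count for surgery against no surgery fell to 0 when most of its mice were left out, each alone, as given above. It also fell to 0 without libraries with over 50% of counts in 10 genes. For susceptible against resilient mice pre 80 of 100 splits gave at least the real 41 genes (highest other 4822), so chance cannot be excluded. The other comparisons had 0 genes by edgeR, which every split matches by construction, so the splits decide nothing about chance there. These were 32 of 32 splits for undefeated mice post against pre (highest other 979, and 3908 in splits that kept the samples of a mouse together) and 100 of 100 for each of the rest. The highest other was 6019, 1014 and 11 for the differences of change (susceptible minus undefeated, resilient minus undefeated, susceptible minus resilient). It was 2998, 3113 and 7378 for susceptible against undefeated, resilient against undefeated and susceptible against resilient mice post surgery, and 1 and 3871 for resilient against undefeated and susceptible against resilient mice without surgery. Why some splits call far more genes than the groups do was not tested.

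Libraries apart from the rest of their group are given as values, and chance alone puts about 1 in 20 groups in this position, which is 10.8 of the 216 tested, against 16 found. In levels of lists (mean log2(CPM + 1)), mouse 11 had an epididymal level of 7.96 pre (next 4.0) and a glucocorticoid level of 4.37 post (next 5.22). Mouse 69 had a fat cell level of 6.86 post (next 3.24), and mouse 61 had a macrophage marker level of 5.51 pre (next 3.17). The respiratory chain level was 4.14 in mouse 39 post (next 4.63) and 5.44 in mouse 52 post (next 4.91). Without surgery, mouse 91 had a ribosomal protein level of 6.05 (next 7.08) and an immediate early level of 6.95 (next 5.93). Mouse 92 had an endothelial level of 3.16 (next 2.72) and a seminal vesicle and prostate level of 3.62 (next 2.92), and mouse 89 had an endothelial level of 2.98 (next 2.49) and a smooth muscle level of 6.07 (next 4.99). Mouse 66 post had 23890305 counted fragments (next 14307948). Mouse 57 post had 46.6% of counts in ribosomal RNA genes (next 16.1%) and 55.8% on the mitochondrial chromosome (next 15.8%), and mouse 61 post had 5.81% in long noncoding RNAs (next 3.76%).

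The difference between classes after defeat was not the same in both cohorts for several lists, as the difference between the surgery and the no-surgery value, permuted within cohorts and adjusted over 17 lists. For susceptible minus undefeated mice it was −1.64 for late spermatid, −2.55 for acrosome and −2.20 for meiotic transcripts (permutation p = 0.00441 for the meiotic list). It was 2.29 for leukocyte, 1.01 for glucocorticoid and 1.66 for immediate early genes (adjusted permutation p = 0.0271 for each). Without mouse 61 these 6 values were −1.71, −2.42, −2.19, 2.46, 1.03 and 1.57, and the immediate early list no longer passed (adjusted permutation p = 0.0532, and 0.0478 or 0.0481 for the other 5). For susceptible minus resilient mice it was −1.57 for late spermatid, −2.71 for acrosome, −2.19 for meiotic, 2.35 for leukocyte, and 2.12 for red blood cell genes. It was 1.30 for smooth muscle, 1.24 for fat cell, 0.61 for endothelial, 1.16 for glucocorticoid, 1.56 for immediate early and 1.36 for interferon genes (adjusted permutation p of 0.0235 to 0.0413). For resilient minus undefeated mice none of the 17 lists passed (adjusted permutation p of at least 0.99). The no-surgery values of susceptible mice include the 4 mice titled ER or D, which cannot be told apart from class. These differences were not computed without them. Nor were they computed without mice 86 or D37, without which few or no germ cell genes were called over all genes in that cohort.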

How the results depend on the processing

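The scores of 4 cell lists, libraries with over 50% of counts in 10 genes left out, and each mouse left out in turn (for the fat cell list mouse 61, 69 or both) were chosen after the data were seen. With RLE size factors or no filter on low counts, every total of called genes, higher and lower together, stayed within 1.5 times its value. The exceptions were resilient mice post against pre (126 with RLE factors) and susceptible against resilient mice without surgery (1 without a filter, against 0). A pseudocount of 0.25 and a mean CPM of 10 left the profile shifts and correlations on the same side of the threshold, but with a mean CPM of 10 the susceptible and undefeated changes had r = 0.766 and another flip of mice 0.774 (exact p = 0.0312). DESeq2 called 5117 genes for susceptible and 903 for resilient mice post against pre, and 40 for undefeated mice. It called 28, 1 and 722 for the differences susceptible minus undefeated, resilient minus undefeated and susceptible minus resilient, and 19 for susceptible against resilient mice pre. It called 596 and 2391 for susceptible against undefeated and resilient mice post surgery, 4141 and 2203 for the same without surgery, and 5247 for surgery against no surgery. Where no reason is given here, the cause of a changed count or direction was not tested. With only the groups compared in the fit, the count was 118 for resilient mice post against pre and 0 for susceptible against resilient mice pre, where fewer samples set the spread. With the other cell score it was 639 for resilient and 120 for undefeated mice post against pre, and 179 for susceptible against undefeated mice without surgery (13 higher and 166 lower, against 1424 and 923).

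With the mouse as a replicate block (paired samples), 451 genes were called for susceptible mice and 0 for resilient mice post against pre. Median absolute changes of the called genes went from 2.50 to 2.16 (median SE 0.728 to 0.764) and from 4.08 to 3.40 (0.874 to 0.927). In susceptible mice 363 of the 992 genes called higher were kept (median 2.43 to 2.41), but 70 of the 1465 called lower (−2.54 to −2.04, SE 0.745 to 0.826). With the scores of 4 cell lists, the counts were 211, 245 and 1420 for susceptible, resilient and undefeated mice post against pre. They were 0 for susceptible against resilient mice pre, susceptible against undefeated mice without surgery and surgery against no surgery. The median absolute change of the called genes fell from 2.50 to 0.29 (median SE 0.728 to 0.685) in susceptible mice, from 4.08 to 0.31 in resilient mice. It fell from 1.58 to 0.56 (0.429 to 0.429) without surgery and from 2.21 to 0.16 for surgery against no surgery. Without libraries with over 50% of counts in 10 genes, 942 genes were called for susceptible mice post against pre (median size of the called genes 2.50 to 2.46, SE 0.728 to 0.770, the same direction in 2452 of 2452), and 0 for susceptible against resilient mice pre. There were 1765 for susceptible against undefeated mice without surgery (749 higher and 1016 lower), 1972 for susceptible against resilient mice without surgery and 0 for surgery against no surgery, where the median change went from 2.21 to 2.06 and its SE from 0.604 to 0.821. Without mouse 61, 263 genes were called for undefeated mice post against pre and 0 for surgery against no surgery. Without the mice titled ER or D, 1431 and 922 were called for susceptible against undefeated and resilient mice without surgery. Against undefeated mice the higher genes went from a median of 1.89 to 2.34 (SE 0.535 to 0.60) and the lower ones from −1.29 to −0.93 (0.349 to 0.477).

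With each mouse left out in turn, the counts ran from 426 to 7160 for susceptible and 0 to 80 for resilient mice post against pre, and 0 to 65 for susceptible against resilient mice pre. They ran from 125 to 4834 for susceptible against undefeated mice without surgery and 0 to 4529 for surgery against no surgery. Where no gene was called with all mice, they ran from 0 to 263 for undefeated mice post against pre, 0 to 2850 for the susceptible minus resilient change, and 0 to 3218 and 0 to 4153 for susceptible against undefeated and resilient mice post surgery. They ran from 0 to 3340 for susceptible against resilient mice without surgery and stayed 0 in the other 4 comparisons. Among these comparisons with no gene called with all mice, the highest counts came without mouse 61 for undefeated mice post against pre. They came without mouse 11 otherwise in the surgery cohort, and without mouse 89 in the cohort without surgery. The profile shift ran from 0.796 to 1.09 in susceptible mice (exact p from 0.0312 to 0.156) and from 0.553 to 0.724 in resilient mice (exact p from 0.0312 to 0.25), with the highest values without mouse 11 and without mouse 54. Without mouse 61 it was 0.6998 in undefeated mice, against 0.460. Of the list calls with the preset correlation, 90 were lost with an estimated correlation and 1 was kept, while with the mouse as a block 62 were kept and 1 was lost.

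Named genes whose fitted change took the other sign included the following. With the scores of 4 cell lists none of them passed (edgeR adjusted p of at least 0.262), so those signs are uncertain. With the scores of 4 cell lists, in susceptible mice post against pre, Prg4 went to −0.63, Cxcl13 to −0.60, Nr4a1 to −0.57, Lcn2 to 1.6 and Catsper4 to 0.12. Spaca1 went to 0.0196, Rnase10 to 2.80, Mylk to 0.13, Pecam1 to −0.33, Vwf to 0.29 and Rsad2 to 0.74. In resilient mice Prg4 went to −0.49, Trim10 to 0.36 and Slc4a1 to 0.21, in undefeated mice Gm29050 to 0.0906, and for surgery against no surgery Hist1h2ba to −0.57 and Gm19951 to 1.98. With DESeq2, Lcn2 went to 1.24 (DESeq2 adjusted p = 0.025, so called in the opposite direction) and Rnase10 to 0.44 (DESeq2 adjusted p = 0.614). With the mouse as a block Lcn2 went to 0.70, and without mouse 61 Igha went to −0.41 for the resilient minus undefeated change and Spp1 to 0.14 for susceptible against undefeated mice post surgery. Simulated 2-fold changes, with each gene drawn independently at the same group sizes, were recovered for 7.46% of genes in susceptible mice post against pre. The share was 25.4% for susceptible against undefeated mice without surgery and 2.99% for surgery against no surgery.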

Other observations

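The macrophage list and all tests of it were chosen after the main results were seen. Macrophage genes that rose in susceptible mice post against pre prompted it, so its rise there is not independent support. Its camera p-values are unadjusted, unlike those of the other lists. Genes that mark large peritoneal macrophages differed in several comparisons. In susceptible mice post against pre, the transcription factor gene Gata6, which sets the identity of these cells, rose from 2.02 ± 1.34 to 13.7 ± 7.54 CPM (log2 change 2.74 ± 0.55, SE, n = 7 each, edgeR adjusted p = 0.00586). Its span overlaps another gene. The phosphatidylserine receptor gene Timd4 rose by 5.63 ± 1.31, the adhesion molecule gene Icam2 by 4.72 ± 1.27, and the coagulation factor genes F10 and F5 by 4.78 ± 1.05 and 3.23 ± 0.71. The macrophage protein gene Cd5l rose by 4.09 ± 0.91, from 4.35 ± 4.26 to 74.9 ± 41.8 CPM. Timd4 and Icam2 were under 1 CPM in the mean of the pre libraries without mouse 61 (0.554 and 0.745), and without these 2 members the median of the list was 1.51 in susceptible, 1.05 in resilient and 0.59 in undefeated mice. In resilient mice 1 member passed over all genes and 9 when adjusted over the list alone (median 2.06, camera p = 0.0576 with an estimated correlation), and the level differed by 1.20 in the mean, higher in 5 of 7 mice (exact p = 0.109). In undefeated mice none passed (median 0.50, camera p = 0.0317 with an estimated correlation) and the level differed by 0.92, higher in 5 of 6 mice (exact p = 0.156). Without mouse 61, whose time points are in doubt, 4 members passed over all genes and 7 over the list alone (median 1.67), and the level differed by 1.42, higher in 5 of 5 mice (exact p = 0.0625, the smallest possible). The difference between the susceptible and undefeated changes had a median of 1.32 with 6 members higher over the list alone (camera p = 0.138 with an estimated correlation, exact p of the level = 0.107). Without mouse 61 it had a median of 0.36 with no member higher, and the level difference went from 1.151 to 0.657 (exact p = 0.236).

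In mice without surgery, Itga6 and Naip1 had been seen among the leading genes of susceptible against undefeated mice before the list was written, so the values of this paragraph leave them out. Of the other 15 genes 9 were lower in susceptible than in undefeated mice. Gata6 differed by −1.43 ± 0.34, and F5 was at 29.0 ± 14.2 against 146 ± 72.4 CPM (−2.34 ± 0.44, SE, n = 6 each, edgeR adjusted p = 0.0106). The span of F5 overlaps another gene. In resilient against undefeated mice all 15 members had values below 0 (median −0.75) and the level differed by −0.64 (exact p = 0.0303, adjusted 0.0848). In susceptible against resilient mice the median was −0.85 (exact p of the level = 0.0152, adjusted 0.0547). With surgery, the level of undefeated mice post differed by −1.08 from that without surgery (exact p = 0.0152, adjusted 0.0547), and by −1.02 without mouse 61 (exact p = 0.0216).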
